A study of Mus musculus with 8 samples.

How the data were processed

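TOX binding was profiled by CUT&RUN, in which an antibody directs a nuclease to its target on chromatin and the released DNA is sequenced. Per the labels, 3 libraries came from sorted TCRSMARTA CD4 T cells of lymph nodes draining B16-GP61 tumours, 7 days after transfer, and 3 from sorted TCRTAG CD8 T cells of liver tumours, 20 days after transfer. The labels also list 2 input libraries of other sorted T cells, which carry no peak list and were not used here. Groups and replicate numbers were taken from the sample titles. The first library of each cell type carries another form of library name than the other 2, which the labels do not explain, so a difference in batch is possible. The labels do not say whether the 3 libraries of a cell type came from separate animals, so p-values over libraries measure only the spread between these samples, which may be technical.

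Each library had 1 peak list, and the peak names inside a list carry that library's name alone, so peaks were compared as called per library. The submitters' processing notes name FastQC 0.12.1, Trim Galore 0.6.6, Bowtie2 2.4.4, Picard, MACS3 3.0.3, deepTools 3.5.1 and the mouse build GRCm38.p6, with no role or order. The control used in peak calling and the caller's settings are not given in the sources used here. For each peak the authors deposited a fold enrichment at the summit (a ratio), the −log10 p and −log10 q, a score equal to the whole part of 10 times the −log10 q, and the summit position. No deposited q exceeded 0.00957. The fold enrichment is the authors' own value for each peak and was used only to describe, rank or filter peaks within 1 list, except that the closing part compares ratios of 2 folds of the same list between lists. Read depth is unknown from peak lists, and a longer list can come from a deeper library as well as from more binding.

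Genes were placed with the RefSeq gene table of the same build, GRCm38.p6, of which 21900 protein-coding genes were used. The table gives no strand, exons or genome sequence. For that reason the planned promoter class became summits within 1000 bp of either end of a protein-coding gene, the remaining summits were divided into those inside and outside genes, and exons, introns and untranslated regions were not assigned. A gene held a peak when a summit lay inside it or within 5000 bp outside either end, in place of the planned 5000 bp upstream. A summit between close neighbours counts for each of them. The planned search for 18 sequence motifs under summits needs a genome and was not run. Of the genes in the 18 fixed lists, 1 (Ighm) did not match a protein-coding gene. Coordinates are 1-based.

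Peaks of all libraries that overlapped by at least 1 bp were merged into regions. A region or gene was called in a cell type when at least 2 of its 3 libraries held a peak. Overlap between lists was measured as the Jaccard index, the base pairs shared by 2 lists over those covered by either. Its mean over pairs of the same cell type minus that over pairs of different cell types was set against the 10 splits of the 6 libraries into groups of 3, as an exact permutation test. The consensus regions of CD8 cells were placed at random 100 times on the same chromosomes. Shares of summits were compared by two-sided exact permutation, whose smallest p for 3 against 3 libraries is 0.1. Single shares carry 95% exact Clopper-Pearson intervals, which cover counting error only.

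Gene lists for T cell programmes, housekeeping genes and markers of 5 other cell types were tested against 10000 random lists drawn from protein-coding genes of the same length decile (two-sided permutation p, Benjamini-Hochberg adjusted over 36 tests, 18 lists in 2 cell types). The smallest p these random lists allow is 0.0002. CD4 and CD8 libraries were compared by each library's share of list genes among its genes with a peak (exact permutation), and over genes by two-sided Fisher's exact tests, both adjusted over 18 lists. The lists, the tests of the report, the rule for named genes and all alternatives but those said to be added were fixed before the data were examined. The rule took up to 4 genes per T cell or housekeeping list with peaks in the most libraries of either cell type, ties going to the higher mean percentile of fold, and the 10 regions per cell type with the highest mean percentile of fold within lists among regions with a peak in all 3 of its libraries. It also took the 10 such regions found in 3 libraries of a cell type and 0 of the other, and 15 genes named whatever their result. Other genes in the text were chosen after their values were seen. A few genes are not reported here by name, but count in the list tests.

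Alternatives covered stricter peaks (−log10 q of 5 or more), lists cut to the 1395 peaks of highest fold so that all were as long as the shortest, other overlap rules, other gene assignments, other numbers of libraries needed, and leaving out each library. No 2 lists were identical, and at most 13 peaks had the same position in a pair of lists. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. Of 200 random lists of 20 genes, the list test called 1.5% with unchanged odds of a peak, and 71.5% (CD4) and 74.5% (CD8) with the odds raised 4 times, among 21900 genes. These rates count p under 0.05 before adjustment. With lists drawn from the 15755 merged regions, the real split ranked first in 8% of 50 sets of lists drawn from 1 pool. It did so in 70% of 50 sets with pools for each cell type, in which part of the regions were drawn more often. The simulated lists were shorter than the real ones and cut to equal length, so these shares do not carry over to the full lists. The number of merged regions and 1 Jaccard index were checked against bedtools 2.31.1.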

Results

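TOX, an HMG-box protein of T cell development and exhaustion, was mapped by CUT&RUN in transferred, tumour-responding mouse T cells sorted as CD44+ PD1hi. The CD4 cells carried the SMARTA receptor, which recognises the GP61 antigen of the B16-GP61 melanoma, and were taken from tumour-draining lymph nodes on day 7. The CD8 cells carried the TCRTAG receptor and were taken from liver tumours of ASTxAlbCre mice on day 20. Cell type, tissue, tumour and day therefore changed together between the groups of 3 libraries. The CD4 lists held 11930, 4069 and 8040 peaks (replicates 1 to 3), which covered 7.67, 1.44 and 3.33 Mb. The CD8 lists held 10806, 4946 and 1395 peaks, which covered 6.62, 2.29 and 0.563 Mb. The longest list had 8.55 times as many peaks as the shortest. Median peak widths were 553, 288 and 343 bp in CD4 libraries and 524, 390 and 341 bp in CD8 libraries.

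The first question was whether TOX occupied the same regions in CD4 and CD8 T cells. Among regions with a peak in all 3 libraries of a cell type, the 10 of highest mean percentile of fold in each cell type included T cell receptor loci. The 2 sets shared 4 regions, and nearly all others had peaks in the libraries of the other cell type as well, at any rank. A region between Trac and Dad1 (chromosome 14, 54224072 to 54229460), downstream of the receptor alpha constant gene, held the peak of highest fold in 5 of the 6 lists, and the third highest in CD4 replicate 2. Its fold was 173, 56.0 and 91.8 in the CD4 lists and 105, 59.3 and 24.7 in the CD8 lists. Regions next to Neat1 and Frmd8 (chromosome 19, 5844963 to 5847081), next to Pkib (chromosome 10, 57743490 to 57744287) and 301 bp from Sp1 (chromosome 15, 102404993 to 102407019) were the others in the leading 10 of both cell types, and were in 6 of 6 libraries.

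The leading CD4 regions further included a pair in the receptor beta locus on chromosome 6, beside Trbv12-2 (41114045 to 41118861) and beside Trbv31 (41552800 to 41555668). Both held peaks in 6 of 6 libraries. Regions at Erh and Slc39a9, Zpbp and Spata48, Fiz1 and Zfp524, and Spns1 completed the CD4 set. The region at Erh was in 3 CD4 and 2 CD8 libraries and the other 3 in all 6. The remaining leading CD8 regions lay inside Bcl2l1, which encodes the survival protein BCL-xL (chromosome 2, 152830246 to 152831973), 11516 bp from Fignl1, and at Vamp2 and Per1, Slc4a9 and Ankhd1, and Tbc1d10b, Mylpf and Septin1. The last was on the unplaced contig GL456216.1 (15433 to 17844), with no protein-coding gene in reach. All 6 of these were in every library of both cell types.

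Merging gave 15755 regions, of which 920 held peaks in all 6 libraries and 5701 (36.2%) in 1 library. CD4 cells had 7206 consensus regions and CD8 cells 4322, and 3412 were shared, or 78.9% of the CD8 regions and 47.3% of the CD4 regions. Random placement of the CD8 regions put 0.631% on CD4 regions on average and 0.879% at most. A further 3794 regions were called in CD4 cells only and 910 in CD8 cells only, but 2548 and 614 of these had a peak in 1 library of the other cell type. These counts changed with the lists used. With 1395 peaks from each list, 554 regions were CD4 only, 472 CD8 only and 700 shared, and without CD4 replicate 1 the full lists gave 1284 CD4-only and 2030 CD8-only regions.

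By the Jaccard index of full lists, libraries of the same cell type overlapped as much as libraries of different cell types. Unequal list lengths cap this index. For CD8 replicates 1 and 3 it was 0.0789, although 94.8% of the shorter list's peaks were overlapped. The mean Jaccard index was 0.243 ± 0.112 (SD, 6 pairs) within and 0.248 ± 0.115 (SD, 9 pairs) between cell types, a difference of −0.00497 that 5 of the 10 splits reached (exact permutation p = 0.5). The highest single pair was CD4 replicate 1 with CD8 replicate 1 (0.446), which with lists of equal length was still the highest pair of different cell types (0.362). With lists of equal length the direction of the difference turned, to 0.322 ± 0.0850 within and 0.270 ± 0.0544 between, a difference of 0.0517 (exact p = 0.1, the smallest possible). The share of the shorter list's peaks found in the longer one went the same way, 90.6 ± 3.82% within against 77.9 ± 11.3% between (exact p = 0.1).

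**Figure D1:**
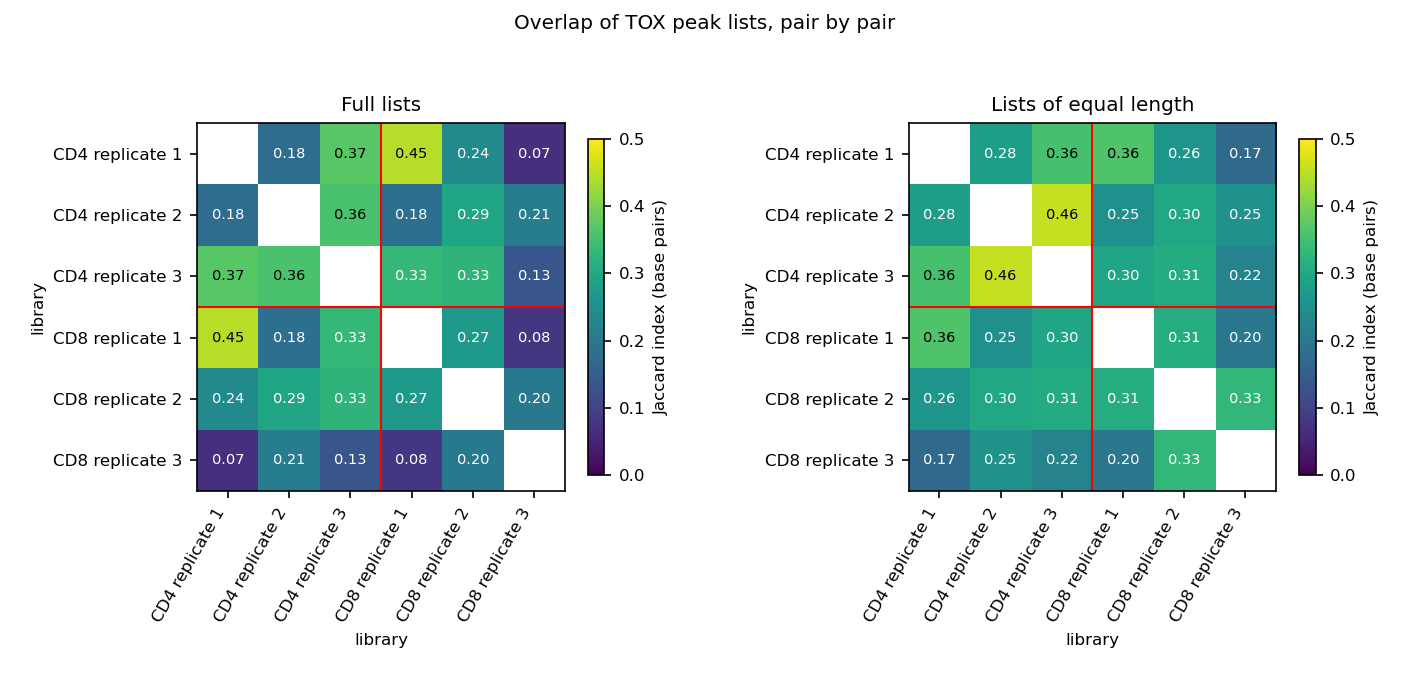
Jaccard index (base pairs shared over base pairs covered) for each pair of the 6 peak lists, as colour and number, for full lists and for the 1395 peaks of highest fold from each list. Red lines part CD4 from CD8 libraries. With full lists the highest value (0.446) joins CD4 replicate 1 and CD8 replicate 1, and with equal lists it joins CD4 replicates 2 and 3 (0.456).

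A peak in every library of one cell type and none of the other was found in 233 regions for CD4 and 20 for CD8. Those of CD4 cells with the highest mean percentile of fold lay at Asf1b and Prkaca (chromosome 8, 83972438 to 83973133, fold 30.3, 13.1 and 23.0), Ramp3, Spsb1, Mroh1, Pptc7, Wwox, Mdm1, Gpr132, Pik3cd and Mknk2. Pik3cd encodes the p110δ subunit of the PI3K of lymphocytes. Genes of the fixed lists with such a CD4 region included Batf, Btla, Cd28, Dgka, Gata3, Id3, Rpl4, Tcf7 and Zbtb7b. The gene of such a region can hold other peaks. Cd28 and Tcf7 had peaks in 2 CD8 libraries, Batf, Btla, Dgka and Gata3 in 1, and Mknk2 in 3, whereas Zbtb7b had them in 0. The leading CD8 regions lay near Tead1 (chromosome 7, 112917726 to 112918754, fold 17.7, 15.1 and 9.07) and Man2b2, in Pik3r6, Nmnat2, Tex14, Arhgap17, Rad51b and Nek6, and beside Tmem128 and Otop1 and beside Irf8. Among all 20 CD8 regions, the list gene was Nr4a2, an orphan nuclear receptor gene linked to exhaustion. It was not at a leading region, and the gene also had a peak in 1 CD4 library.

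No single region can pass a test of 3 against 3 libraries. The number of such regions changed with the lists used as well. Equal lists gave 69 for CD4 and 81 for CD8. The CD4 count was 1097 without CD4 replicate 2 and 1174 without CD8 replicate 1, and the CD8 count 281 without CD8 replicate 3 and 77 without CD4 replicate 1.

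Peaks of both cell types concentrated at gene ends. Summits within 1000 bp of an end of a protein-coding gene made up 50.1 ± 4.02% (SD, n = 3) of CD4 peaks and 51.8 ± 5.36% (SD, n = 3) of CD8 peaks, against 3.03 to 3.66% of randomly placed peaks. Per library the share ran from 46.4% (95% interval 45.5 to 47.4) in CD8 replicate 1 to 57.1% (54.5 to 59.7) in CD8 replicate 3. A further 26.3 ± 2.86% of CD4 and 25.7 ± 3.47% of CD8 summits lay elsewhere inside genes. The cell types did not differ by more than the spread between libraries (exact permutation p = 0.7 for gene ends, n = 3). With lists of equal length the direction turned, to 65.9 ± 0.849% for CD4 and 62.2 ± 4.41% for CD8 (exact p = 0.1, n = 3).

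Regions shared by both cell types were at gene ends more often than those called in 1 cell type. The share was 59.7% (95% interval 58.0 to 61.4) of shared regions, 44.4% (42.8 to 46.0) of CD4-only regions and 33.1% (30.0 to 36.2) of CD8-only regions. CD8-only regions lay inside genes away from the ends in 39.1% and CD4-only regions in 29.4%. The odds of a gene end were 1.62 times higher in CD4-only than in CD8-only regions (Fisher's exact test, two-sided, p = 3.98e-10, over regions, which are not independent replicates). Against shared regions Fisher's exact tests gave p = 2.04e-38 for CD4-only and 9.25e-47 for CD8-only regions. These classes depend on list length. Of the 3794 CD4-only regions 2548, and of the 910 CD8-only regions 614, had a peak in 1 library of the other cell type. Over libraries the gene-end share of summits showed no clear difference with full lists (exact permutation p = 0.7). With equal lists it was higher in CD4 libraries, as in the region contrast (65.9 against 62.2%, exact permutation p = 0.1, the smallest possible). Tests of 3 against 3 libraries cannot decide this. The contrast of regions is therefore not read as a difference in binding, nor as its absence.

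The next question was which T cell programmes carried TOX peaks. Genes of T cell receptor signalling had the highest share of genes with a peak in both cell types, 28 of 30 in CD4 and 22 of 30 in CD8 cells. These were 2.74 and 3.20 times the mean of length-matched random lists (both adjusted permutation p = 0.0012). Ribosomal protein and housekeeping genes stood at 2.93 and 2.45 times, so in CD4 cells the receptor list did not exceed them. Both receptor calls ended with equal lists and with gene-end summits alone. Cd3d, a receptor subunit, Malt1 and Cblb, an E3 ligase that restrains T cell activation, had peaks in 6 of 6 libraries, and Fyn in 3 CD4 and 2 CD8 libraries. Genes of inhibitory receptors and exhaustion had peaks in 17 of 25 (CD4, fold 2.02, adjusted permutation p = 0.00589) and 16 of 25 (CD8, fold 2.85, adjusted p = 0.0012). Both calls ended with equal lists and with gene-end summits alone. The CD8 call also ended without CD8 replicate 2 and with 3 of 3 libraries needed. Pdcd1, which encodes PD-1, Nr4a3 and Nfatc1 had peaks in 6 of 6 libraries, with Pdcd1 at a highest fold of 38.6, 15.9 and 17.9 in CD4 lists and 35.6, 20.0 and 8.48 in CD8 lists. Nr4a1 had peaks in 3 CD4 and 2 CD8 libraries, as had Tox itself and Ctla4, and Havcr2 had none.

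T lineage transcription factor genes had peaks in 17 of 20 (CD4, fold 2.44, adjusted permutation p = 0.0012) and 13 of 20 (CD8, fold 2.76, adjusted p = 0.0024). Ets1 and Tcf3 had them in 6 of 6 libraries, Lef1 and Runx3 in 3 CD4 and 2 CD8 libraries, and Foxp1 in 3 and 1. Adhesion and migration genes passed in both cell types, with 12 of 19 (fold 2.00, adjusted permutation p = 0.0211) and 10 of 19 (fold 2.48, adjusted p = 0.0161). The fold fell under 1 with equal lists (0.694 and 0.748), where Itga4 alone of the list had peaks in at least 2 libraries of a cell type. With gene-end summits alone it was 0.958 in CD4 cells. In CD8 cells it was 0.781 with 3 of 3 libraries needed, where 1 gene counted, and 0.775 without CD8 replicate 1. Itga4, an integrin gene, had peaks in 6 of 6 libraries, Cxcr4 and Itgal in 3 and 2, and S1pr1 in 3 and 1. Ribosomal protein and housekeeping genes passed too, with 28 of 36 in CD4 cells (fold 2.93, adjusted permutation p = 0.0012) and 16 of 36 in CD8 cells (fold 2.45, adjusted p = 0.0024). Rps19 had peaks in 6 of 6 libraries, Rpl32 in 3 and 2, and Rps14 in 3 and 1.

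Naive, memory and stem-like genes had peaks in 16 of 20 in CD4 cells (fold 2.45, adjusted permutation p = 0.0012) and 9 of 20 in CD8 cells (fold 2.04, adjusted p = 0.0673). In CD8 cells they passed with the nearest gene end within 50000 bp (fold 2.48, adjusted permutation p = 0.0247), without length matching (fold 2.26, Fisher's exact test, adjusted p = 0.0218) and with summits near gene ends left out (fold 5.55, adjusted permutation p = 0.000654). Bach2 had them in 6 of 6 libraries and Tcf7, which encodes TCF-1, in 3 CD4 and 2 CD8 libraries. Follicular helper genes had peaks in 13 of 16 in CD4 cells (fold 2.45, adjusted permutation p = 0.0024) and 6 of 16 in CD8 cells (fold 1.72, adjusted p = 0.341). The CD4 call ended without CD4 replicate 1 (fold 1.66, adjusted permutation p = 0.502) or replicate 3 (fold 1.58, adjusted p = 0.556), and with 3 of 3 libraries needed (fold 1.65, adjusted p = 0.721). Bcl6, the lineage factor of follicular helper cells, had peaks in 6 of 6 libraries, Maf in 3 and 2, and Btla in 3 and 1. Regulatory T cell genes had peaks in 9 of 15 in CD4 cells (fold 1.91, adjusted permutation p = 0.0673) and 8 of 15 in CD8 cells (fold 2.54, adjusted p = 0.0259). In CD4 cells they passed in the same 3 alternatives (fold 2.32, 2.02 and 5.12). In CD8 cells the fold fell under 1 without CD8 replicate 1 (0.973) or 2 (0.934) and with 3 of 3 libraries needed (0.990). These values rest on 1 gene, since CD8 replicate 3 held a peak in 1 gene of the list, and show no clear turn. With gene-end summits alone the fold was 0.967. Ikzf4 had peaks in 6 of 6 libraries, Tnfrsf18 in 3 and 2, Tgfb1 in 3 and 1, and Foxp3 in none.

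Proliferation genes did not pass in either cell type (12 of 23 in CD4, adjusted permutation p = 0.134, and 7 of 23 in CD8, adjusted p = 0.528), although Myc, Ccnd2, Ccnd3 and Mcm7 had peaks in 6 of 6 libraries. In CD4 cells they passed in those 3 alternatives too (fold 1.95, 1.76 and 3.03). TH2 and TH17 genes had peaks in 3 of 15 in each cell type (adjusted permutation p = 0.581 and 1), among them Rora and Ccr4, with 3 CD4 and 2 CD8 libraries each. Ahr had peaks in 1 CD4 and 2 CD8 libraries. Of 18 lists, 7 lay above random lists in each cell type, ribosomal protein and housekeeping genes among them. With summits within 1000 bp of a gene end alone, 1 list (CD4) and 0 lists (CD8) did, and with 1395 peaks per list none did. The CD4 list that stayed was that of ribosomal protein and housekeeping genes, so no T cell list stayed. Without CD8 replicate 1 or 2, when both remaining libraries were needed, 2 and 1 of the CD8 lists lay above.

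**Figure D2:**
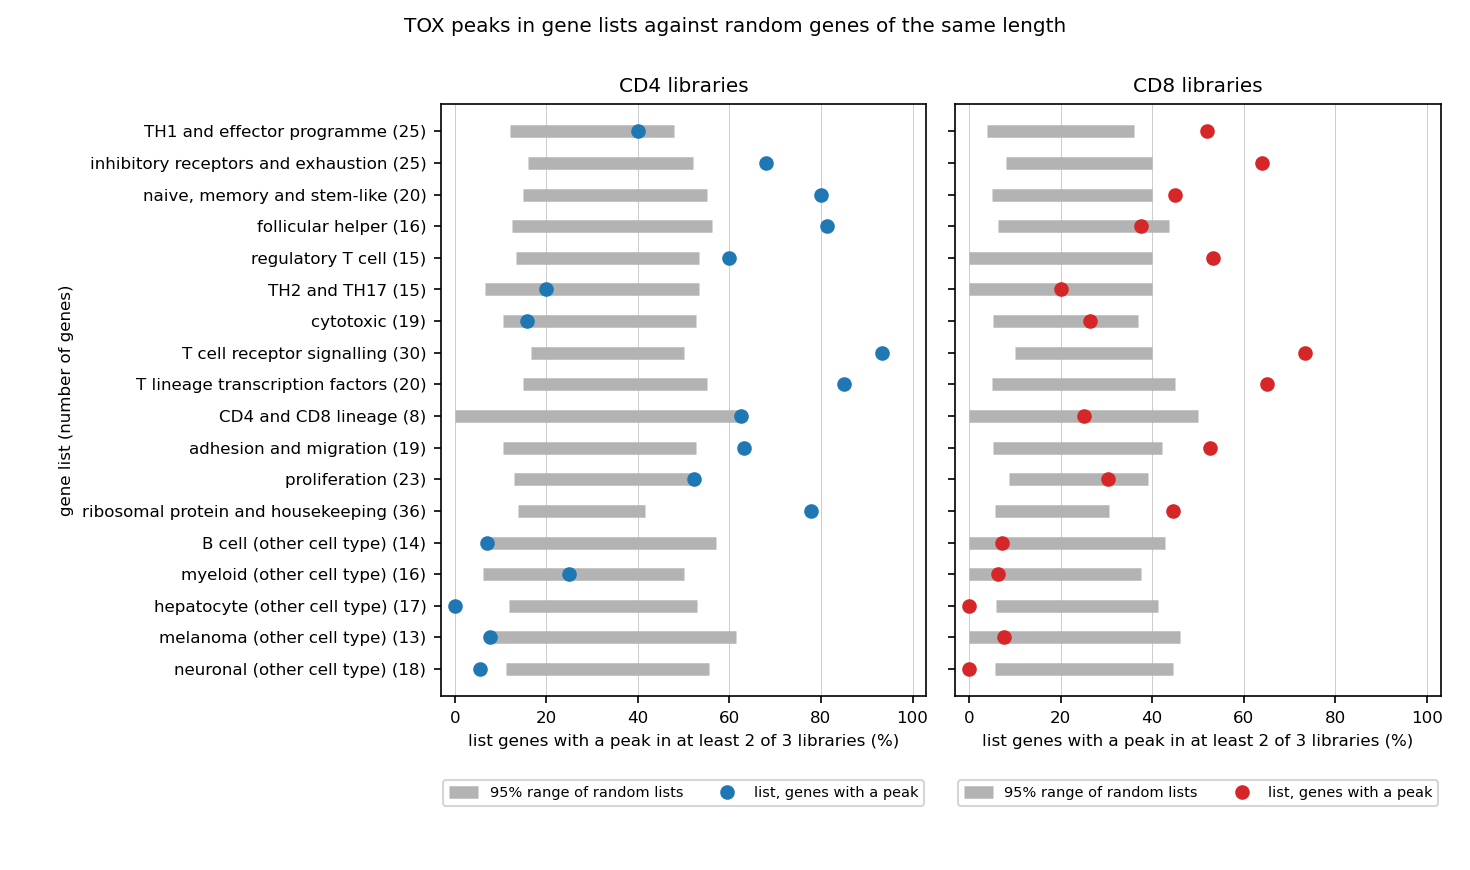
Percent of the genes of each fixed list with a peak in at least 2 of 3 libraries, for CD4 (blue) and CD8 (red) libraries. Grey bars span the central 95% of 10000 random lists of genes of the same length, and numbers in parentheses give the genes per list. T cell receptor signalling lies farthest to the right, at 93.3% in CD4 and 73.3% in CD8 libraries, and the hepatocyte list lies at 0% in both.

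The title of the study names TH1 function of CD4 cells, so TH1 and effector genes were examined by name. In CD4 cells 10 of 25 had peaks, 1.33 times the random mean (adjusted permutation p = 0.462), and in CD8 cells 13 of 25, 2.56 times the random mean (adjusted p = 0.0036). With summits given to the nearest gene end within 50000 bp the list passed in CD4 cells too (12 of 25, fold 1.95, adjusted permutation p = 0.0324), as it did with summits near gene ends left out (fold 2.91, adjusted p = 0.0420, a pass that depends on the draw of the random lists). Stat4 and Irf1, which act in IL-12 and interferon responses, and Id2 had peaks in 3 CD4 and 2 CD8 libraries, and Ifngr1 in 2 and 3. Tbx21, which encodes the TH1 lineage factor T-bet, had none in CD4 libraries and a peak in 1 CD8 library (fold 5.15). Ifng had none in CD4 libraries and peaks in 2 CD8 libraries (fold 9.43 and 5.91), and Cxcr3 had none in any library. The difference in libraries with a peak, CD4 minus CD8, turned for Ifng from −2 to 1 when summits were given to the nearest gene end within 50000 bp, and for Stat4 from 1 to −2 with equal lists. The CD8 call ended without CD8 replicate 1 (adjusted permutation p = 1) or replicate 2 (adjusted p = 1), with 1395 peaks per list (adjusted p = 1), and with gene-end summits alone (adjusted p = 0.75).

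The difference between the cell types was then tested list by list. Among TH1 and effector genes, those called in CD4 cells only included Eomes, and Ifng, Ccl5, Ccl4, Il2ra and Nkg7 were called in CD8 cells only (Fisher's exact test, adjusted p = 0.0361 over 18 lists). This call was lost in 7 of 8 alternatives, with adjusted p of Fisher's exact test from 0.0263 without CD8 replicate 3 to 1 without CD8 replicate 2 and with equal lists. Among cytotoxic genes, Srgn and Cx3cr1 were called in both cell types, Eomes in CD4 cells only, and Nkg7, Prf1 and Klrc1 in CD8 cells only (Fisher's exact test, adjusted p = 0.146). Gzmb had no peak in any library. The cytotoxic list did not lie above random lists in either cell type (3 of 19 in CD4, adjusted permutation p = 0.401, and 5 of 19 in CD8, adjusted p = 0.687).

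As a share of all genes with a peak, cytotoxic genes made up 0.0387 ± 0.0116% (SD, n = 3) in CD4 and 0.0953 ± 0.0254% (SD, n = 3) in CD8 libraries, without overlap between the groups (exact permutation p = 0.1, adjusted p = 0.6). These shares rest on 4, 1 and 3 genes in CD4 and 9, 5 and 1 in CD8 replicates 1 to 3, so a single gene can end the separation. Genes of the CD4 and CD8 lineages made up 0.0817 ± 0.0175% and 0.0350 ± 0.0316% (exact permutation p = 0.1, adjusted p = 0.6, n = 3), and the sign of this difference turned with equal lists. Myeloid genes, markers of another cell type, stood at the same p (0.0547 ± 0.0117% and 0.0196 ± 0.0185%, exact permutation p = 0.1, adjusted p = 0.6, n = 3). An exact test of 3 against 3 libraries cannot give a p under 0.1, so none of the 18 lists could pass. By gene, Zbtb7b, which encodes the CD4 lineage factor ThPOK, had peaks in 3 CD4 and 0 CD8 libraries (fold 15.2, 6.36 and 8.77), Cd4 in 2 and 0, and Gata3 in 3 and 1. Cd8a had a peak in 1 CD8 library, and Nr4a2 in 1 CD4 and 3 CD8 libraries. With equal lists Zbtb7b, Cd4, Gata3 and Cd8a had no peak in any library, and Nr4a2 had peaks in 0 CD4 and 3 CD8 libraries. The lineage list as a whole had peaks in 5 of 8 genes in CD4 cells (adjusted permutation p = 0.268) and 2 of 8 in CD8 cells (adjusted p = 1). In CD4 cells it passed with the nearest gene end within 50000 bp (fold 2.71) and with summits near gene ends left out (fold 4.94).

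**Figure D3:**
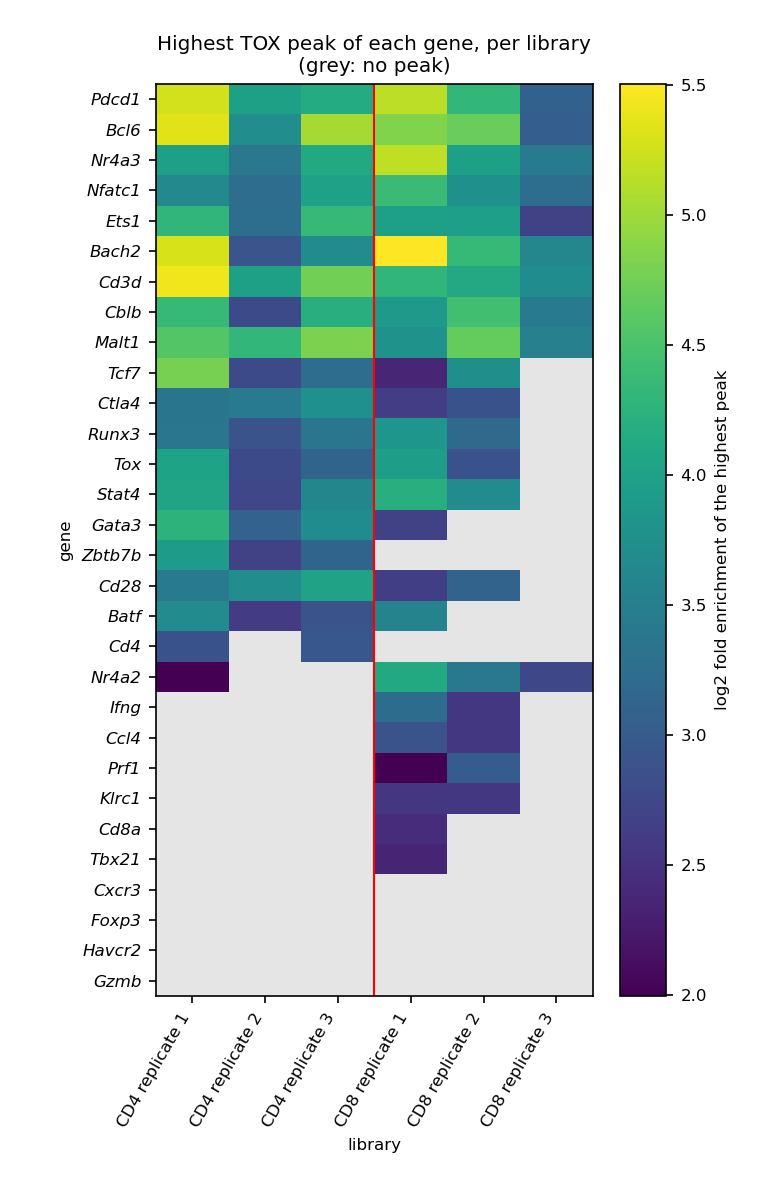
Fold enrichment (log2 colour scale) of the highest peak inside or within 5000 bp of each named gene in each of the 6 libraries, with grey where the list had no peak there. Folds are the authors' values and rank peaks within 1 column only. Pdcd1 and Bcl6 have peaks in all 6 libraries, Zbtb7b in the 3 CD4 libraries, and Cxcr3, Foxp3, Havcr2 and Gzmb in none.

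Markers of 5 other cell types were tested in the same way. None of the 17 hepatocyte genes held a peak in any of the 6 libraries, CD8 libraries from liver tumours included, against 3.58 genes in random lists for CD8 (adjusted permutation p = 0.0673) and 5.30 for CD4 (adjusted p = 0.0096). Neuronal genes lay below random lists in CD4 (1 of 18, adjusted permutation p = 0.0378) and CD8 cells (0 of 18, adjusted p = 0.0402). The neuronal call was lost in CD8 cells in every alternative and in CD4 cells in all but 2 (without length matching and without CD4 replicate 2), and the hepatocyte call in CD4 cells with equal lists, gene-end summits alone, summits near gene ends left out, 3 of 3 libraries needed, and without CD4 replicate 1 or 3. B cell genes had 1 of 14 in each cell type (adjusted permutation p = 0.123 and 0.424), myeloid genes 4 of 16 and 1 of 16 (adjusted p = 1 and 0.424), and melanoma genes 1 of 13 in each (adjusted p = 0.127 and 0.446). The melanoma gene was Pmel, which lies within 5000 bp of Rab5b, Cdk2 and Dgka and held a summit inside the gene in 6 of 6 libraries.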

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

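Lists of equal length, the splits of the libraries and the gene lists were planned. Their use in this part to weigh explanations was set after the result was seen. The exception is the test of T cell lists with summits near gene ends left out. It was added after the main results but before its own outcome was known.

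Peaks outside the protein-coding genes stood out because no comparison of genes used them. The peak between Trac and Dad1 reached a fold of 173 in CD4 replicate 1 and 24.7 at the lowest, in CD8 replicate 3. The peak between Trbv13-1 and Trbv12-2 ran from 146 in CD4 replicate 1 to 5.49 in CD8 replicate 3. A peak on the unplaced contig GL456216.1 was in 6 of 6 lists, at a fold of 18.1 to 48.2. Each list also held 2 wide peaks on the mitochondrial genome, of which the highest had a fold of 4.42 to 13.9. No input peak list was used here, so none of these was set against a control. Groups of 3 libraries were not tested for outlying values.

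More regions were called in CD4 cells only than in CD8 cells only, 4.17 times as many with full lists. With lists of equal length the ratio was 1.17, but that cut left nearly equal numbers of consensus regions (1254 in CD4 and 1172 in CD8 cells), which holds the ratio near 1 whatever the cause. Longer CD4 lists, which read depth may set, and a wider binding of TOX in CD4 cells therefore cannot be told apart. Of regions with a peak in every library of one cell type and none of the other, the real split gave 253 with full lists and the highest other split 1330, so that 3 of the 10 splits gave as many. That other split parts the 3 longest lists from the 3 shortest, a structure of the samples by list length. With equal lists the real split gave 150, the highest other 49, and 1 of the 10 splits gave as many, but 10 splits are too few for a share under 0.05.

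T cell gene lists carried peaks more often than random genes of the same length, and so did ribosomal protein and housekeeping genes. A test left out summits within 1000 bp of any end of a protein-coding gene. If peaks at the ends of active genes were the whole cause, at most 1 called T cell list should then stay above random lists. All 6 of the 6 called lists in CD4 cells did, which argues against peaks at these outer gene ends as the whole cause. Start sites inside genes and ends of noncoding genes were not left out, so peaks at other promoters stay open. The loss of the T cell calls with gene-end summits alone had been seen when this test was set. For hepatocyte chromatin, 0 of 17 hepatocyte genes had a peak in CD8 cells, where random lists held 1 at the lower end of their 95% range. The list did not pass in CD8 cells (adjusted permutation p = 0.0673). CD4 libraries, which came from lymph nodes, also had 0 of 17, so this count cannot decide on hepatocyte chromatin. Cutting of open T cell chromatin regardless of the antibody stays open and cannot be told apart from TOX binding here, since housekeeping genes also stood at 2.93 times the random mean in CD4 cells and no input peak list was used.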

How the results depend on the processing

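Most alternatives were planned. Leaving out summits near gene ends, equal lists with the replicate block, and equal lists without both first libraries were added after seeing the data. Of 898 alternative values, 661 were counted as kept, 76 fell short of the threshold, 14 passed it, 110 moved and 37 were counted as turned. Kept values stayed on their side of the threshold or, for counts, equal or close to the main value. Gene lists whose fold crossed 1 without a call in either setting were counted as kept, so the 37 leave these out. For example, TH1 genes in CD4 cells went from 1.33 to 0.551 with equal lists. The exact permutation tests have a smallest p of 0.1 or more, so none of them changed side of the threshold. Motif alternatives were not run, since no genome was used. Read depth is unknown, and the short CD8 replicate 3 list limits what 2 or 3 of 3 CD8 libraries can show. Except where the construction shows it (fewer peaks or libraries), the cause was not tested.

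Overlap within minus between cell types was −0.00497 with full lists. It turned to 0.0517 with equal lists (exact p = 0.1), to 0.127 as the share of the shorter list's peaks (exact p = 0.1), 0.0234 with reciprocal overlap of 50% (exact p = 0.3), 0.0381 without both first libraries (exact p = 0.333), and 0.122 with equal lists without both. Leaving out 1 library gave −0.0573 to 0.0653, above 0 without CD8 replicate 1 or 2. With 3 libraries per cell type, the data cannot settle whether replicate numbers pair the samples. Deviations of same-numbered libraries correlated at −0.124, −0.0207 and −0.0866, and those of different numbers at −0.0863 to 0.155. In equal lists the correlations were 0.0585, 0.0209 and 0.00532 for the same number and −0.0572 to 0.0459 for different numbers. Of pairs of different cell types, the first libraries had the highest Jaccard index in equal lists (0.362). With the replicate block the overlap stayed at −0.00497 and, in equal lists, 0.0517 (exact p = 0.25 for both, the smallest possible), and no call changed. The gene-end difference of −1.62 points turned to 3.73 with equal lists and ran from −4.29 to 1.07 with 1 library left out, above 0 without CD8 replicate 3.

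Regions in CD4 only, CD8 only and both numbered 554, 472 and 700 with equal lists. A peak in 1 library sufficing gave 2896 CD8-only and 8512 shared regions, and 3 of 3 libraries gave 270 and 920. With 1 library left out they ran from 1284 (without CD4 replicate 1) to 6085 (without CD8 replicate 1) for CD4 only, 93 (without CD8 replicate 1) to 2030 (without CD4 replicate 1) for CD8 only, and 1121 to 3337 for both. Regions in every library of one cell type and none of the other numbered 69 (CD4) and 81 (CD8) with equal lists, and ran from 235 to 1174 and from 20 to 281 with 1 library left out.

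Lists above random numbered 7 in each cell type. They numbered 0 and 0 with equal lists, and 1 (CD4, the housekeeping list) and 0 (CD8) with gene-end summits alone. With the nearest gene end within 50000 bp they numbered 11 (CD4). CD8 lists above random numbered 1 with peaks in 3 of 3 libraries, and 1 to 7 with 1 library left out.

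With equal lists, folds over random lists without a call were 1.19 (TH1, CD8), 2.64 and 3.37 (exhaustion, CD4 and CD8), 2.70 (naive, CD4), 2.404 (follicular, CD4), 1.89 (regulatory, CD8), 3.10 and 2.33 (receptor signalling), 1.98 and 2.13 (T lineage factors), 3.30 and 3.14 (housekeeping), and 0 for hepatocyte (CD4) and neuronal genes (both). Adhesion turned to 0.694 and 0.748, values that rest on Itga4 alone. With gene-end summits alone they were 1.49 (TH1, CD8), 1.93 and 1.40 (exhaustion), 2.08 (naive, CD4), 2.11 (follicular, CD4), 1.98 and 1.94 (receptor signalling), 1.66 and 1.90 (T lineage factors), 1.13 (adhesion, CD8), 2.402 (housekeeping, CD8), 0 (hepatocyte, CD4) and 0.275 and 0 (neuronal), and turned for regulatory genes (CD8, 0.967) and adhesion (CD4, 0.958).

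With peaks in 3 of 3 libraries calls ended at 1.24 (TH1, CD8), 3.42 (exhaustion, CD8), 1.65 (follicular, CD4), 3.38 (T lineage factors, CD8), 1.74 (adhesion, CD4), 2.78 (housekeeping, CD8), 0 (hepatocyte, CD4) and 0 (neuronal, both). Those counted as turned, at 0.990 (regulatory, CD8) and 0.781 (adhesion, CD8), rest on 1 gene of each list. With −log10 q of 5 or more they ended at 2.36 (regulatory, CD8), 1.24 (adhesion, CD8), 0.189 and 0 (neuronal). Without length matching 2.26 (naive, CD8), 2.02 (regulatory, CD4) and 1.76 (proliferation, CD4) passed and neuronal genes (CD8, 0) did not. With the nearest gene end within 50000 bp 1.95 (TH1, CD4), 2.48 (naive, CD8), 2.32 (regulatory, CD4), 2.71 (lineage, CD4) and 1.95 (proliferation, CD4) passed, and neuronal genes (0.390 and 0) did not.

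With summits near gene ends left out, 2.91 (TH1, CD4, depending on the draw of the random lists), 5.55 (naive, CD8), 5.53 (follicular, CD8), 5.12 (regulatory, CD4), 4.94 (lineage, CD4) and 3.03 (proliferation, CD4) passed, and 1.11 and 2.87 (housekeeping), 0 (hepatocyte, CD4) and 0 (neuronal, both) did not. With 1 library left out the folds ran from 1.17 to 2.62 (TH1, CD8), 2.90 to 3.39 (exhaustion, CD8), 1.58 to 2.53 (follicular, CD4), 0.934 to 2.60 (regulatory, CD8), 2.82 to 3.35 (T lineage factors, CD8), 1.66 to 2.07 (adhesion, CD4), 0.775 to 2.30 (adhesion, CD8), 2.53 to 2.80 (housekeeping, CD8), 0 to 0 (hepatocyte, CD4), 0 to 0.172 (neuronal, CD4) and 0 to 0 (neuronal, CD8). Of these, CD4 calls ended without replicate 1 or 3. CD8 calls among them ended without replicate 1 or 2, except exhaustion without replicate 1 and neuronal genes, which also lost theirs without replicate 3.

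Differences in list share, CD4 minus CD8 in percent, turned with equal lists to −0.0209 (TH2 and TH17), 0.0453 (receptor signalling) and −0.0406 (lineage), and with the nearest gene end to −0.00913 (B cell). With 1 library left out they ran from −0.000757 to 0.0176 (B cell), −0.123 to 0.00858 (receptor signalling), −0.00376 to 0.0400 (TH2 and TH17), −0.0225 to 0.00999 (adhesion), −0.0267 to 0.000201 (melanoma) and −0.0110 to 0.0545 (regulatory). Between genes called in one cell type only, the TH1 list's share differed by −0.858 points (Fisher's exact test), and by −0.237 (adjusted p = 1) with equal lists, −0.831 (adjusted p = 0.0622) with the nearest gene end, and −1.75 to −0.436 with 1 library left out. Of 65 named genes, 128 values were equal to the main value, 61 moved and 6 turned sign. CD4 minus CD8 libraries with a peak turned to −1 for Ccr4, Cxcr4 and Tox and −2 for Stat4 with equal lists, and with the nearest gene end to −1 for Foxp1 and 1 for Ifng. Of 36 named regions, 54 values were equal to the main value, 18 moved and none turned. All 18 were of regions found in 3 libraries of a cell type and 0 of the other, mostly with equal lists. For example, the difference at Mknk2 went from 3 to 1, while that at Prkaca stayed at 3.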

Other observations

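The tests in this part were chosen after the result was seen, with these exceptions. The counts of regions with equal lists were planned. Leaving out summits near gene ends was added after the main results but before its own outcome was known.

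Summits within 1000 bp of any end of a protein-coding gene were left out. T cell receptor signalling genes then had peaks in 22 of 30 in CD4 cells and 15 of 30 in CD8 cells. These were 5.61 and 5.84 times the random mean (adjusted permutation p = 0.000654 for both). Follicular helper genes had peaks in 10 of 16 in CD4 and 5 of 16 in CD8 cells, and inhibitory receptor and exhaustion genes in 14 of 25 and 11 of 25. Ribosomal protein and housekeeping genes had 2 of 36 in CD4 cells (fold 1.11, adjusted permutation p = 1) and 3 of 36 in CD8 cells (fold 2.87, adjusted p = 0.268). The TH1 and effector list had 6 of 25 in CD4 cells and 7 of 25 in CD8 cells, with an adjusted p of 0.0420 for CD4 that another draw of the random lists put above the threshold. Cytotoxic and TH2 and TH17 genes did not pass in CD4 (adjusted permutation p = 0.384 for both) or CD8 cells (adjusted p = 0.161 for both), nor did lineage (adjusted p = 0.962) and proliferation genes (adjusted p = 0.119) in CD8 cells. No test compared the T cell lists with the housekeeping list.

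Among the 1395 peaks of highest fold per list, 69 regions were in 3 CD4 and 0 CD8 libraries and 81 the other way round. This cut keeps the whole list of CD8 replicate 3 but a part of the 11930 peaks of CD4 replicate 1, and only 1 of the 69 and 2 of the 81 regions were free of peaks in the full lists of the other cell type. They are therefore not read as a difference between cell types.

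The beta chain locus gave a hypothesis. The peak between Trbv13-1 and Trbv12-2 had 0.850 ± 0.0171 (SD, n = 3) of the fold of the peak between Trac and Dad1 in the same CD4 list, and 0.317 ± 0.0825 (SD, n = 3) in the CD8 lists. A candidate explanation is the receptor transgene of the CD4 cells, since SMARTA T cells use a beta chain of the Trbv13 family. However, the summits lay between Trbv13-1 and Trbv12-2, outside both (41118543 to 41118650). Whether the transgene carries that stretch is not known from the labels. The values did not overlap, but the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and the labels do not name the transgene's segments, so this stays open, as does a difference between lists in how fold scales. An equal gain over the whole beta locus is argued against, since the relative fold of the peak between Trbc2 and Trbv31 was 0.676 ± 0.0564 (SD, n = 3) in CD4 and 0.524 ± 0.0086 (SD, n = 3) in CD8 lists, and the factor between cell types was 2.08 times larger beside Trbv12-2. Of the other 2 regions of the locus with peaks in at least 2 libraries of each cell type, that at 41532125 to 41533642 had a factor of 0.517 (CD4 over CD8) and that at 41541072 to 41550844 one of 1.84, with no peak in CD8 replicate 3, so a gain of part of the locus stays open.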
